A study of Mus musculus with 2 samples.

How the data were processed

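H3K4me3, the trimethylation of lysine 4 of histone H3 that marks promoters, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole kidneys of C57BL/6NCrl mouse embryos on embryonic day 16.5 (E16.5). Kidneys of male and female embryos were pooled, per the labels. The samples form 1 group of 2 biological replicates; 41 embryos went into replicate 2, and the number for replicate 1 is not given in the labels used here. No second tissue, stage or treatment entered the comparisons, so each test below is within this group. The ChIP alignments, the control library and signal tracks were not analysed here.

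The authors deposited 4 lists of peaks in mm10 coordinates. Per the text files deposited beside them, 1 list was called on the filtered alignments of each replicate against a control, 1 on the alignments of both replicates pooled, and the replicated list was derived from the pooled list and both replicate lists. The caller, the aligner, their settings and the overlap required for the replicated list are not given in the sources used here. Each peak carries the authors' fold, a linear ratio of ChIP over control, and the −log10 of the peak's p and q, as the authors computed and deposited them. The smallest −log10 p was 2.05 in replicate 1, 2.00 in replicate 2, 2.03 in the pooled list and 2.14 in the replicated list. These folds belong to single peaks of single lists and were used here only to describe, rank and filter peaks within a list. Read totals are not part of the lists, so sequencing depth is unknown, and confidence intervals below (Wilson, 95%) cover counting error over regions or genes only.

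No peaks overlapped within any list, so merging overlapping peaks changed nothing. All replicated peaks were also in the pooled list, and 0 peaks ran past the ends of the 21 chromosomes of the reference, GRCm38, the assembly that mm10 names. Peaks on unplaced contigs (12, 10, 12 and 11 in the replicate 1, replicate 2, pooled and replicated lists) were left out of the comparisons. Genes and transcription start sites (TSSs) came from GENCODE release M21: a protein-coding gene's TSSs were the starts of all its protein-coding transcripts, and a promoter was the window of 1000 bp on either side. A gene counted as carrying a peak when a peak overlapped any of its promoters. Promoters were classed by the ratio of observed to expected CpG dinucleotides within 500 bp of the TSS, as low (under 0.35), middle or high (over 0.6), using the gene's highest TSS. Regions away from coding promoters were classed in turn as lncRNA promoter, exon, intron or intergenic. Coordinates are 1-based.

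Replicate regions were called shared when the other replicate's peaks covered at least 50% of their length, and the share was compared with 1000 circular shifts along each chromosome (1-sided permutation test). The share of replicated regions at coding promoters was compared with 1000 shifts in the same way. Fixed gene lists were compared with all other protein-coding genes by 2-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over 24 lists and a threshold of 0.05. Of 321 listed genes outside the lists defined by symbol patterns, 319 were matched, 2 of them through a synonym; Ahsp and Hemgen were not matched, and 4 noncoding members (H19, Kcnq1ot1, Meg3 and Xist) were described but not tested. Domains were replicated peaks joined over gaps of up to 1000 bp. A list's median domain width was compared with 10000 random lists of equal size drawn from genes with a domain in the same CpG classes (2-sided permutation test, Benjamini-Hochberg adjusted over 23 lists with at least 3 members in domains). Genes are not replicates: these tests describe sets of promoters in these libraries, and neighbouring genes that share a domain are not independent. Widths given as mean ± SD are over domains built the same way from each replicate's own list (n = 2).

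The gene lists, tests and alternatives were set before the data were examined. Named genes followed a rule set at that time: the genes of the 20 widest domains, at most 4 per domain; for each list the 2 members with the widest domains and the first 2, alphabetically, without a peak; all members of Hox groups 10 to 13 and of the sex chromosome list; the 5 widest domains over 5000 bp from any coding TSS; and the 5 promoter peaks with the largest fold. Other genes are named as examples chosen after their values were seen. Alternatives covered the promoter window, the TSS used, stricter −log10 q (at least 5) and fold (at least 5) limits, the pooled list, each replicate alone, the overlap rule, the joining gap and the background genes; the repeated shift tests among them used fewer shifts, with a smallest possible p of 0.00498. The closing section gives their effect.

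The procedures were tried on simulated data. For the overlap comparison, 70.4% of 19783 simulated regions were planted as shared and 70.4% were measured, and unrelated lists gave a permutation p of 0.584. For list occupancy over 20000 simulated genes, 20 of 20 planted higher lists and 20 of 20 planted lower lists were called, as was 1 of 40 lists drawn at random. For domain width over 13365 simulated genes with a domain, 15 of 20 planted lists were called wider and 0 of 40 random lists were called. The count of unique 32-mers used in the closing section was not tried on simulated data. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.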

Results

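H3K4me3 peaks were mapped in E16.5 mouse kidney, a stage at which nephron progenitors, forming nephrons, the branching ureteric tree, stroma and vessels are present together. Replicate 1 had 33605 peaks covering 37.2 Mb, with a median width of 737 bp. Replicate 2 had 31490 peaks covering 39.5 Mb, with a median width of 908 bp. The pooled list held 31722 peaks and the replicated list 27113 peaks covering 39.2 Mb, with a median width of 1199 bp. Peaks with a q over 0.05 made up 3.36% of the replicate 1 list, 2.36% of the replicate 2 list and 0.114% of the replicated list (31 peaks).

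The first comparison asked how far the replicates found the same regions. Of 33593 regions in replicate 1, 28226 (84.0%, 95% CI 83.6 to 84.4) were shared with replicate 2, and 25280 of 31480 (80.3%, CI 79.9 to 80.7) in the other direction. The mean was 82.2% ± 2.63 (SD, n = 2 directions). Circular shifts shared 1.51% and 1.40% on average (permutation p = 0.000999 in each direction, the smallest that 1000 shifts can give). Sharing followed the authors' fold. With regions ranked into 10 equal bins of fold, in the lowest bin 38.4% of replicate 1 regions and 29.4% of replicate 2 regions were shared, while the 5 highest bins of replicate 1 and the 4 highest of replicate 2 were shared at 100%. Regions not covered over at least 50% of their length by the other replicate were weak and narrow, with a median fold of 3.15 and width of 211 bp in replicate 1, against 14.5 and 1023 bp for shared regions. In replicate 2 these medians were 3.37 and 257 bp against 22.7 and 1286 bp. By length, 34.8 Mb lay in peaks of both replicates, 93.6% of the replicate 1 total and 88.1% of the replicate 2 total.

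**Figure D1:**
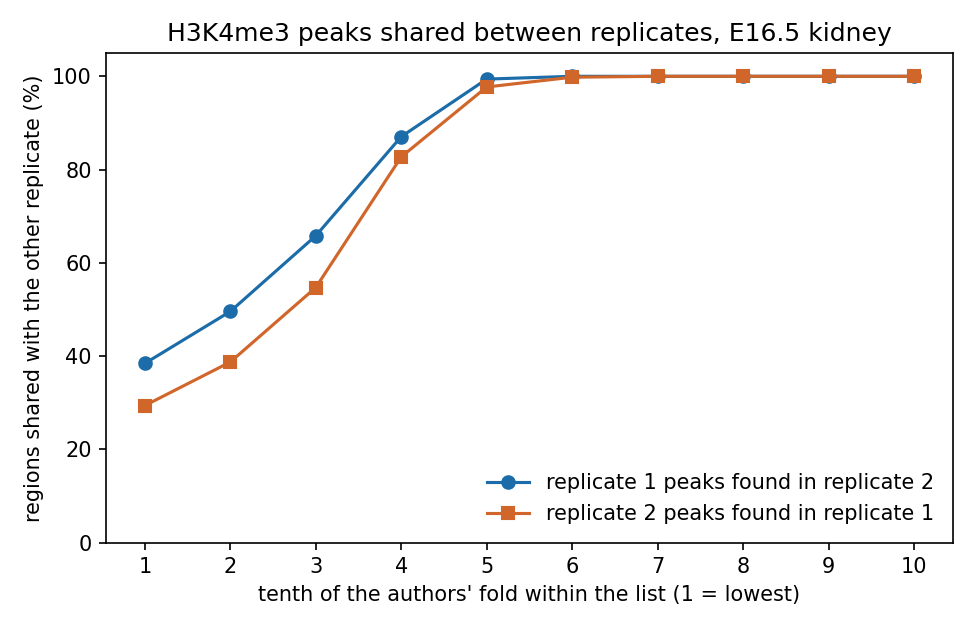
Share of each replicate's H3K4me3 regions (y axis, percent) covered over at least 50% of their length by the other replicate's peaks, in 10 equal bins of the authors' fold within each list (x axis, 1 the lowest); circles are replicate 1 and squares replicate 2. The share rose from 38.4% and 29.4% in the lowest bin to 100% in the highest.

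The replicated list kept 27113 of the 31722 pooled peaks (85.5%, CI 85.1 to 85.9). Coding promoters lost the least: 95.8% of pooled peaks there were kept, against 83.8% at lncRNA promoters, 80.2% of intergenic, 76.3% of exonic and 66.0% of intronic peaks. The 4609 peaks left out had a median fold of 2.89 and a median width of 219 bp, and 2008 of them were intronic. Only 22.7% of the lowest of 10 equal bins of pooled peaks by fold was kept, and all of the 6 highest bins. Of the peaks left out, 3808 touched a peak of 1 replicate, 704 of neither and 97 of both. Any overlap of 1 bp with both replicates would keep 82.4% of pooled peaks, less than the 85.5% kept. Some peaks of the replicated list therefore did not touch a peak in both replicates. For 1936 of the 27113 kept, coverage by at least 1 replicate fell short of that used above to call regions shared.

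The next comparison asked where the peaks lay. Of 27102 replicated regions, 15518 (57.3%, CI 56.7 to 57.8) lay within 1 kb of a protein-coding TSS, and they held 78.8% of the bases. Circular shifts placed 4.21% there on average and 6.16% at most, so the observed share was 13.6 times that of the shifts (1-sided permutation p = 0.000999, the smallest possible). In the replicates' own lists the share was 50.8% and 51.6% (51.2% ± 0.595, SD, n = 2). A further 4.50% lay at lncRNA promoters, 5.02% in exons, 14.4% in introns and 18.8% between genes. Regions at coding promoters had a median width of 1852 bp and a median fold of 44.2, against 478 bp and 4.54 in introns and 570 bp and 6.13 between genes. From the lowest to the highest of 10 equal bins of fold the share at coding promoters rose from 14.8% to 98.9%. The largest folds were at the promoters of the chaperone genes Hsp90aa1 (90.5) and Hsp90ab1 (89.7), of Gpatch8 (90.5), of Bdp1, a subunit of the RNA polymerase III factor TFIIIB (88.8), and of the zinc finger gene Zfp629 (88.4).

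A replicated peak lay at the promoter of 14642 of 21853 protein-coding genes (67.0%, CI 66.4 to 67.6), and the replicates' own lists gave 67.4% ± 0.165 (SD, n = 2). CpG-rich promoters were almost all marked: 11081 of 11243 genes in the high CpG class (98.6%), 2785 of 3618 in the middle class (77.0%) and 776 of 6992 in the low class (11.1%). The odds ratio of high against low was 548, and Fisher's exact p was below the smallest number that double precision can hold. Peaks at low CpG promoters were also weaker, with a median fold of 10.3 against 54.7 at high CpG promoters, and narrower, with a median domain of 1.24 kb against 2.35 kb. Of 13374 lncRNA genes, 3125 (23.4%) carried a promoter peak. On autosomes 68.2% of coding genes carried a peak, on chromosome X 52.3% (496 of 948) and on chromosome Y 4 of 183. Chromosome X had relatively more genes in the low CpG class (393 of 948, against 6443 of 20722 on autosomes). Within the high, middle and low classes the shares were 94.9%, 67.3% and 10.7% on X. On autosomes they were 98.7%, 78.2% and 11.4%, so part of the gap went with CpG class.

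Promoters of kidney cell types were then compared with those of other cells and organs. Of genes that mark nephron progenitors, early nephrons and podocytes, 16 of 16, 15 of 15 and 15 of 15 carried a promoter peak. Each list passed Fisher's exact test against all other genes, of which 67.0% carried one (Benjamini-Hochberg adjusted exact p = 0.00628, 0.00829 and 0.00829). Among them were the progenitor regulators Six2, Sall1, Wt1 and Pax2, the early nephron genes Lhx1, Pax8 and Wnt4, and the slit diaphragm genes Nphs1 and Nphs2, whose peaks were weak (folds 5.72 and 10.6). Stromal genes carried peaks in 16 of 17 cases (adjusted exact p = 0.0283), the exception being Ren1, which encodes renin; with an authors' fold of at least 5 required, this call was lost (88.2%, adjusted exact p = 0.0939). Ureteric bud and collecting duct genes did in 17 of 19, without passing the test (adjusted exact p = 0.0639), although the list passed with only the outermost TSS (0.0422); Foxi1, a regulator of intercalated cells, and Avpr2, the vasopressin V2 receptor, had none. Proximal tubule genes carried peaks in 12 of 16 cases and loop of Henle and distal tubule genes in 9 of 15, neither different from other genes (adjusted exact p = 0.629 for both). Only 1 and 4 members of these lists were in the high CpG class. The test did not match on CpG class, so it does not compare them with promoters of like CpG content. In the proximal list the apical receptor gene Lrp2 had a fold of 26.3 and Slc34a1, a phosphate transporter, of 6.35, while Slc3a1, Slc5a12, Slc5a2 and Spp2 had no peak. In the loop and distal list Umod, Slc12a1, Slc12a3 and Cldn16, genes of mature thick ascending limb and distal tubule, had none in either replicate. By contrast Clcnkb had peaks of 0.175 and 0.233 kb in both replicates that the replicated list does not hold, and Kcnj1 had 1 of 2.16 kb in replicate 2 alone.

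Among other cell types of the organ, all 18 endothelial genes carried a peak (adjusted exact p = 0.00514), including Kdr, Cdh5, Tek and Sox17. Of 16 macrophage and leukocyte genes only Coro1a did (6.25%, adjusted exact p = 7.87e-06). Adgre1, Aif1 and Csf1r had none, and Ptprc, Spi1, Cd68 and Tyrobp had peaks of 0.195 to 0.246 kb in replicate 2 alone. The replicates' own lists gave 12.5% and 31.2%. Erythroid genes carried peaks in 5 of 14 cases (adjusted exact p = 0.0298): Tal1, Epor, Klf1, Nfe2 and Gypa did, and Alas2 and Epb42 did not. With only the outermost TSS of each gene the share was the same and the call was lost (adjusted exact p = 0.0648). The globin genes Hba-a1 and Hbb-bs also had none, but near-identical gene copies can lose reads in alignment, so these are uncertain. In the list of the adjoining adrenal gland, 5 of 15 genes carried a peak (adjusted exact p = 0.0176); the steroidogenic genes Cyp11a1 and Cyp11b1 had none and Nr5a1 and Fdx1 did.

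Hepatocyte genes carried a peak in 3 of 16 cases (adjusted exact p = 0.000492), skeletal muscle genes in 5 of 16 (adjusted exact p = 0.00983) and germ line genes in 3 of 16 (adjusted exact p = 0.000492). The hepatocyte genes Ahsg and Alb, the muscle genes Acta1 and Cacna1s and the germ line genes Asz1 and Ddx4 were among those without one. Some of the peaks that were found also covered the start of a neighbouring gene: that at Apoh (fold 47.7) covered a TSS of Prkca, that at Actn3 (71.9) one of Zdhhc24 and that at Mylpf (69.9) one of Tbc1d10b. By contrast 20 of 21 regulators of other lineages (adjusted exact p = 0.00829) and 15 of 16 forebrain neuron genes (adjusted exact p = 0.0415) carried a peak, among them Pax6, Sox2, Nkx2-1 and Foxg1; the exceptions were Neurod6 and Nkx2-5, although Nkx2-5 had peaks of 0.175 and 0.195 kb in the replicates. With an authors' fold of at least 5 required, 66.7% of the regulators were left, and their call was lost (adjusted exact p = 1.00), as was that of the forebrain genes (87.5%, adjusted exact p = 0.0939). The forebrain call was also lost with promoters of 500 bp on either side (adjusted exact p = 0.131) and with only the outermost TSS (0.0838), and that of the regulators with −log10 q of at least 5 (85.7%, 0.0848). Housekeeping genes (18 of 18, adjusted exact p = 0.00514), cell cycle genes (16 of 16, adjusted exact p = 0.00628) and Hox genes of paralog groups 1 to 9 (27 of 27, adjusted exact p = 0.000278) were all marked, and 3 of 1134 olfactory receptor genes were (0.265%, the Fisher's exact p again below double precision). Imprinted genes (11 of 12, all but Ndn), the sex chromosome list (8 of 8), Hox groups 10 and 11 (6 of 6) and Hox groups 12 and 13 (5 of 6) did not pass (adjusted exact p = 0.144, 0.0748, 0.214 and 0.671). With promoters of 2 kb on either side all imprinted genes, Ndn included, carried a peak and the list passed (adjusted exact p = 0.0211).

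In all, 10 of 24 lists carried peaks more often than other genes, 7 less often and 7 did not pass, and 18 had an unadjusted exact p under 0.05. Within the high CpG class 0 lists were higher and 1, the germ line list, was lower. That class is too close to fully marked for a higher call, and most lower lists have few members in it, so this does not separate the lists from CpG content.

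**Figure D2:**
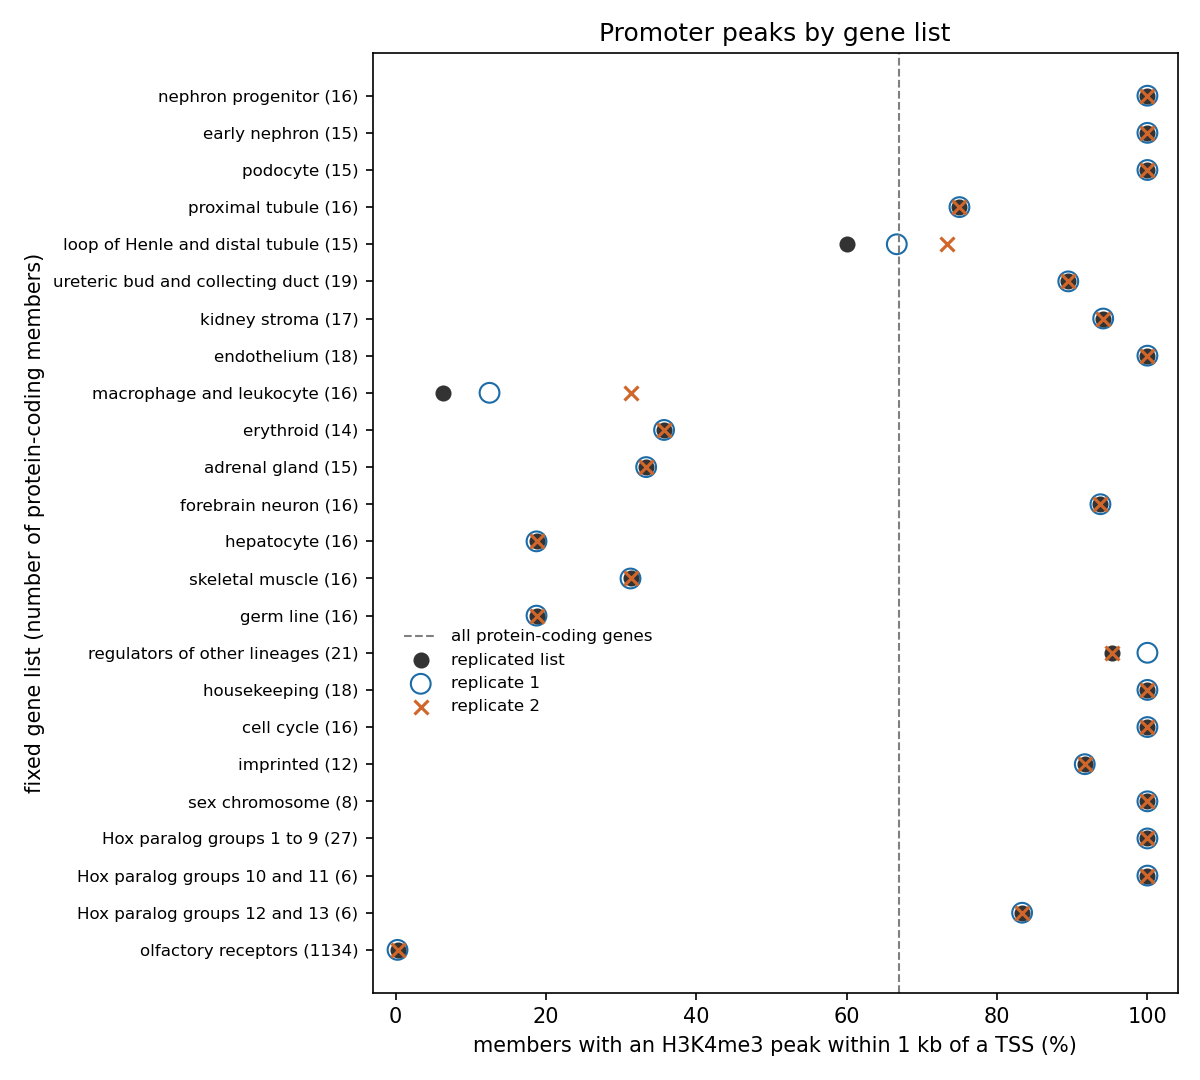
Share of each fixed gene list's protein-coding members with an H3K4me3 peak within 1 kb of a TSS (x axis, percent; list sizes in parentheses on the y axis) in the replicated list (filled circles), replicate 1 (open circles) and replicate 2 (crosses); the dashed line is all protein-coding genes, 67.0%. Nephron progenitor, early nephron, podocyte and endothelial lists stood at 100%, and macrophage, hepatocyte and germ line lists below 20% in the replicated list.

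Taking all kidney lists together, 100 of 113 genes (88.5%) carried a promoter peak, against 46 of 85 genes (54.1%) of the forebrain, liver, muscle, germ line and other-lineage lists together (odds ratio 6.52, 2-sided Fisher's exact p = 7.99e-08). In the replicates' own lists the shares were 89.8% ± 0.626 and 54.7% ± 0.832 (SD, n = 2). Among high CpG promoters 64 of 64 kidney genes and 32 of 41 other genes were marked (Fisher's exact p = 0.000117), but 8 of the 9 unmarked genes were germ line genes and the other was Nkx2-5. Without the germ line list 30 of 31 other genes in that class were marked, and no difference was found (exact p = 0.326). In the middle class 20 of 21 kidney genes and 13 of 21 other genes were marked (exact p = 0.0205), and in the low class 16 of 28 and 1 of 23 (exact p = 6.18e-05). The unmarked middle class genes included the germ line genes Dmrtb1, Piwil1, Piwil2, Stra8 and Tex101, while Dppa3 was marked. The middle class was not compared without the germ line list, so its difference may rest on that list. The low class held no germ line list gene. The last 3 comparisons were chosen after seeing the data. Where present, kidney peaks had a median fold of 31.4 against 10.9, and a median domain width of 4.29 kb against 1.56 kb.

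The 20 widest domains included 5 at Hox genes. The widest ran for 60.7 kb over Hoxb3 to Hoxb9 (chromosome 11: 96269521 to 96330239), with 53.4 ± 1.20 kb in the replicates' own lists (SD, n = 2), where Hoxb9 formed a separate domain of 5.49 ± 0.371 kb. Next was a domain of 47.6 kb from Hoxa5 to Hoxa11, which also covers a TSS of Hoxa3 (chromosome 6: 52202366 to 52249961; 49.0 ± 1.97 kb). It was followed by 1 of 38.2 kb from Hoxd11 to a TSS of Hoxd3 (chromosome 2: 74678398 to 74716590; 38.3 ± 0.266 kb), and 1 of 26.0 kb over Hoxc9 and Hoxc10 (chromosome 15: 102959342 to 102985343; 25.9 ± 0.0205 kb). Outside the clusters, Nr2f2, an orphan nuclear receptor gene, lay in 25.3 ± 0.156 kb, Meis2 in 22.9 kb (22.5 and 23.5 kb in the replicates), Gata3, a regulator of the ureteric epithelium, in 23.3 ± 0.643 kb, and Pax2, needed for both ureteric bud and nephron, in 19.9 ± 1.02 kb. Tbx2 (16.4 ± 0.447 kb), Tbx3 (16.3 ± 0.125 kb), Meis1 (14.5 ± 0.151 kb), Emx2 (14.9 ± 0.706 kb), Sim1 (13.7 ± 0.383 kb), Six2 (13.6 ± 0.706 kb) and Sall1 (12.7 ± 0.297 kb) followed. Zfp503 (12.6 ± 2.61 kb), Smad7 (13.6 ± 1.10 kb), Bahcc1 (14.5 ± 0.470 kb) and the demethylase gene Kdm6b (12.9 ± 0.194 kb) completed the 20, with Hoxd4, whose domain was 9.53 kb in replicate 1 and 19.9 kb in replicate 2. For comparison, the median domain of a protein-coding gene with a promoter peak was 2.17 kb.

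Within the Hox clusters domain widths varied within and between paralog groups. Hoxa10 and Hoxa11 lay in the 47.6 kb domain, Hoxd10 and Hoxd11 in the 38.2 kb domain and Hoxc10 in the 26.0 kb domain, while Hoxc11 had 3.73 ± 0.380 kb (n = 2). In groups 12 and 13 the widths were, for Hoxa13 1.65 ± 0.00778 kb, Hoxd13 1.98 ± 0.599 kb, Hoxd12 2.89 ± 1.50 kb, Hoxc13 1.38 ± 0.0509 kb and Hoxb13 0.643 ± 0.0735 kb (n = 2 for each), and Hoxc12 had no promoter peak. Some members of groups 1 to 9 had domains of similar width, such as Hoxb1 (1.51 ± 0.0834 kb), Hoxc5 (1.95 ± 0.155 kb), Hoxd1 (2.00 ± 0.0205 kb) and Hoxc4 (2.17 ± 0.0530 kb). Median widths were 38.2 kb for groups 1 to 9 and for groups 10 and 11 (adjusted permutation p = 0.000511 for both by the permutation test, the smallest it can give here), and 1.57 kb for groups 12 and 13 against 2.04 kb in random lists (adjusted permutation p = 0.298, not called narrower). The groups were not tested against each other. Genes of a cluster share domains, so their widths are not independent.

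**Figure D3:**
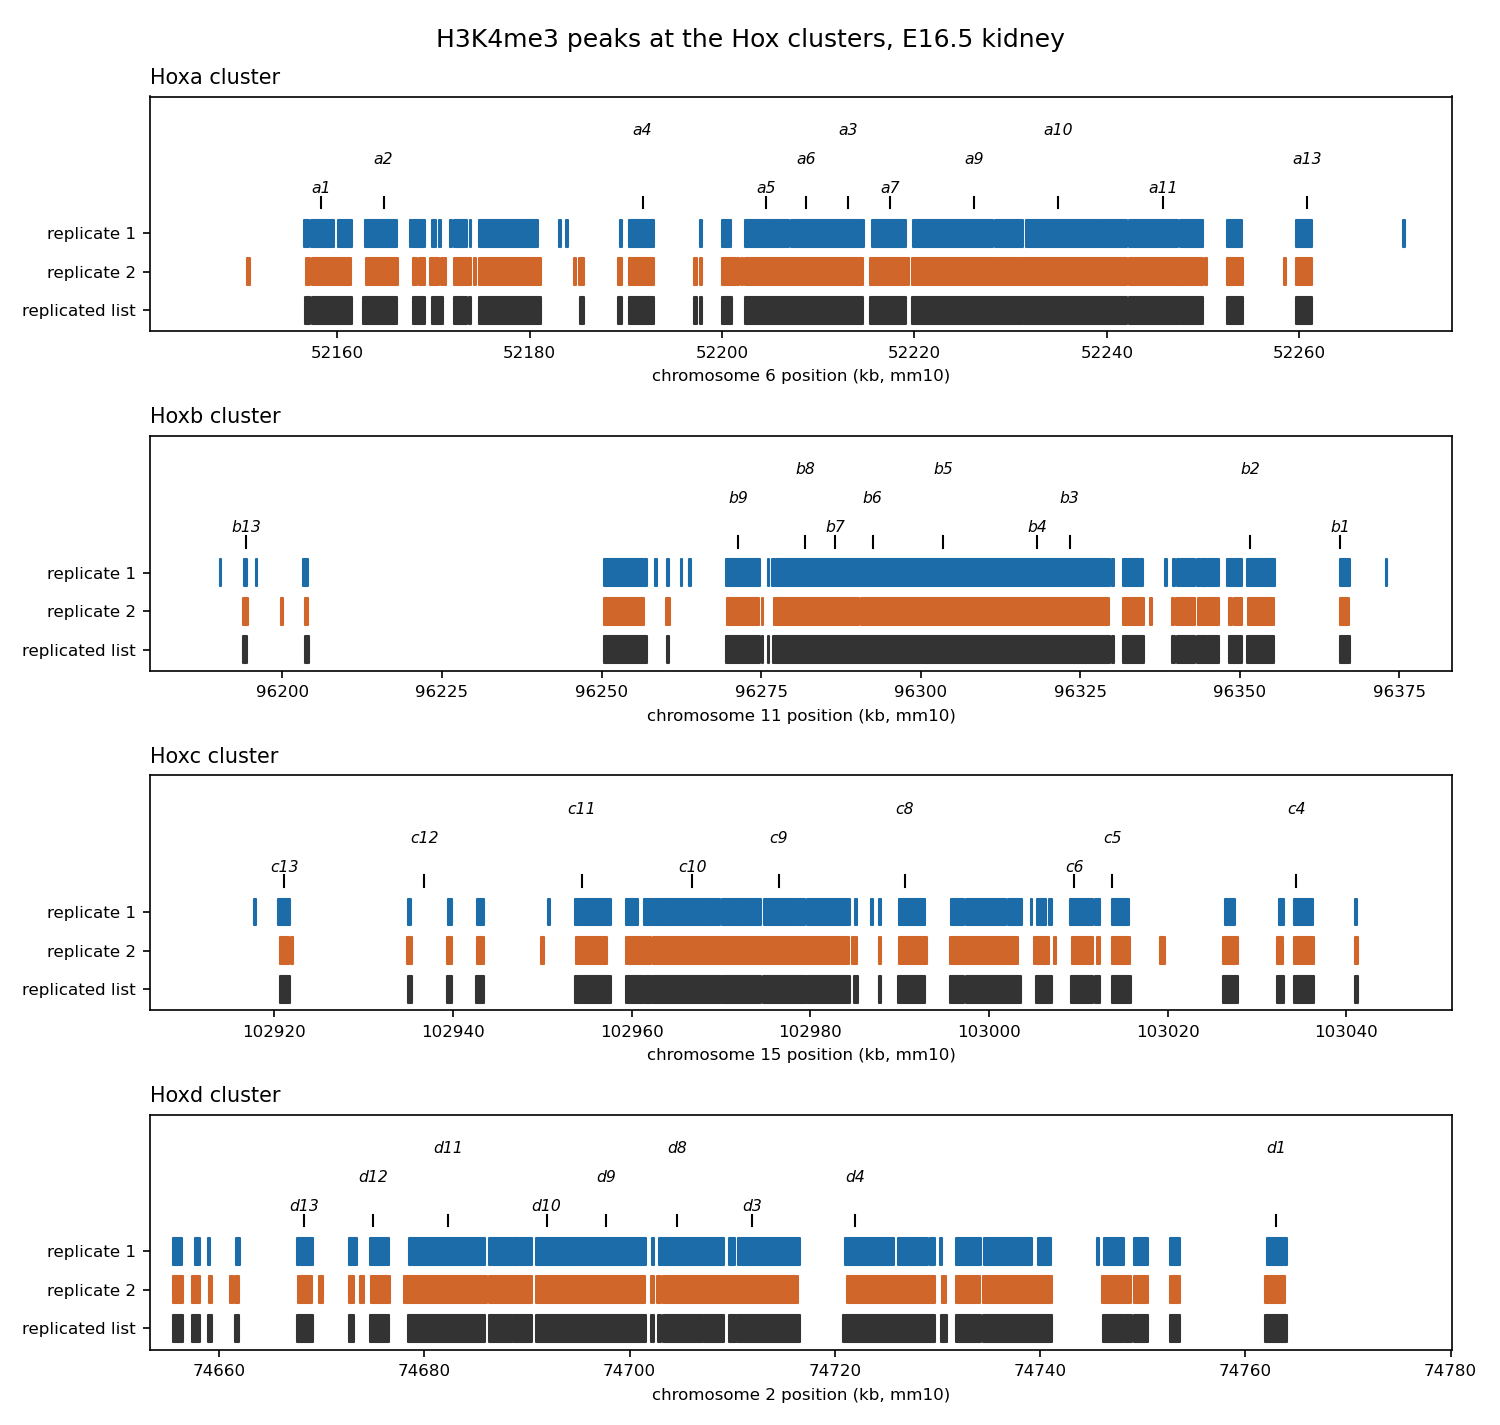
Map of H3K4me3 peaks (bars) at the Hoxa, Hoxb, Hoxc and Hoxd clusters in replicate 1, replicate 2 and the replicated list, against mm10 position in kb (x axis of each panel); ticks with italic names mark 1 TSS of each gene. Hoxa5 to Hoxa11, Hoxb3 to Hoxb9, Hoxc9 to Hoxc10 and Hoxd3 to Hoxd11 lie under nearly continuous peaks, while Hoxa13, Hoxb13, Hoxc13, Hoxd12 and Hoxd13 lie under short peaks and Hoxc12 under none.

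Domain widths of the lists were compared with those of random lists of the same CpG classes. The tests used medians from the replicated list, while values given as mean ± SD are medians from the replicates' own lists. Nephron progenitor genes had a median width of 8.31 ± 0.196 kb (n = 2; 8.61 kb in the replicated list, 2.17 kb in random lists), early nephron genes 7.03 ± 0.135 kb, podocyte genes 3.81 ± 0.0481 kb, stromal genes 4.30 ± 0.150 kb and endothelial genes 3.39 ± 0.141 kb, each with the smallest adjusted permutation p that the permutation test can give here, 0.000511. Ureteric bud and collecting duct genes had 3.47 ± 0.107 kb (adjusted permutation p = 0.000836) and proximal tubule genes 2.36 ± 0.191 kb (adjusted permutation p = 0.0293), and both were also wider than random lists, although the proximal tubule call was lost in 4 of the alternatives. Loop of Henle and distal tubule genes did not differ (1.57 ± 0.164 kb, adjusted permutation p = 0.534). The widest members were Hoxa11 and Hoxd11 among progenitor genes, Pou3f3 (12.6 ± 0.160 kb) and Lhx1 (10.8 ± 0.0587 kb) in early nephrons, Tcf21 (11.4 ± 0.00849 kb) and Foxc2 (9.33 ± 0.442 kb) in podocytes. In the other lists they were Lrp2 (5.92 ± 0.0170 kb) and Pdzk1 (5.47 ± 0.245 kb) in proximal tubule, Sim1 and Tfap2b (9.65 ± 0.0870 kb) in the distal list, Hoxb7 and Gata3 in the ureteric list, Meis2 and Meis1 in stroma, and Egfl7 (9.28 ± 1.44 kb) and Sox17 (7.36 ± 0.174 kb) in endothelium. Without Hox genes, an alternative chosen after seeing the data, the progenitor median was 6.28 kb (adjusted permutation p = 0.000571).

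Housekeeping genes (3.82 ± 0.267 kb, adjusted permutation p = 0.000511; widest Actb and Polr2a), cell cycle genes (2.95 ± 0.200 kb, adjusted permutation p = 0.0184; widest Mki67 and Rrm2) and imprinted genes (3.30 ± 0.176 kb, adjusted permutation p = 0.0270) also had wider domains than random lists. Igf2 at 11.1 ± 1.35 kb and Mest at 7.37 ± 0.172 kb were the widest imprinted genes. The cell cycle call was lost with gaps of up to 3 kb (adjusted permutation p = 0.0644) and without replicate 2 (0.0731), and the imprinted call with gaps of 0 bp (0.0644) and without replicate 2 (0.0529). Regulators of other lineages had narrower domains (1.34 kb in the replicated list against 2.28 kb in random lists, adjusted permutation p = 0.000511). So did the 3 hepatocyte genes with a domain (0.681 kb, adjusted permutation p = 0.0240), the 3 germ line genes (0.450 kb, adjusted permutation p = 0.000836) and the 3 olfactory receptor genes (0.375 kb, adjusted permutation p = 0.0126). In the replicates' own lists these 4 medians were 1.51 ± 0.442, 0.643 ± 0.0566, 0.430 ± 0.0622 and 0.330 ± 0.0230 kb. For regulators of other lineages the narrower width depended on the joining gap. With gaps of up to 3 kb their median was 2.79 kb, above random lists (adjusted permutation p = 0.234). They also had weak peaks. Against random lists matched on the authors' fold, chosen after seeing the data, their median was no longer narrower (adjusted permutation p = 0.503). The fold-matched lists were not also matched on CpG class. Of the 4 lists only olfactory receptor genes kept their call in the comparison matched on fold. Germ line (450 against 1128 bp, adjusted permutation p = 0.0745) and hepatocyte medians (681 against 1255 bp, 0.296) were still lower without passing. Forebrain neuron genes did not differ from CpG-matched lists (2.24 ± 0.141 kb, adjusted permutation p = 0.867). Matched on fold in place of CpG class they were called wider (1988 against 1219 bp, adjusted permutation p = 0.0449). The erythroid, adrenal, skeletal muscle and sex chromosome lists did not differ from CpG-matched lists either (adjusted permutation p = 0.867, 0.109, 0.370 and 0.256). The adrenal list was called narrower without replicate 2 (1.06 kb, 0.0297). In all 12 of 23 lists were wider, 4 narrower and 7 did not pass.

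**Figure D4:**
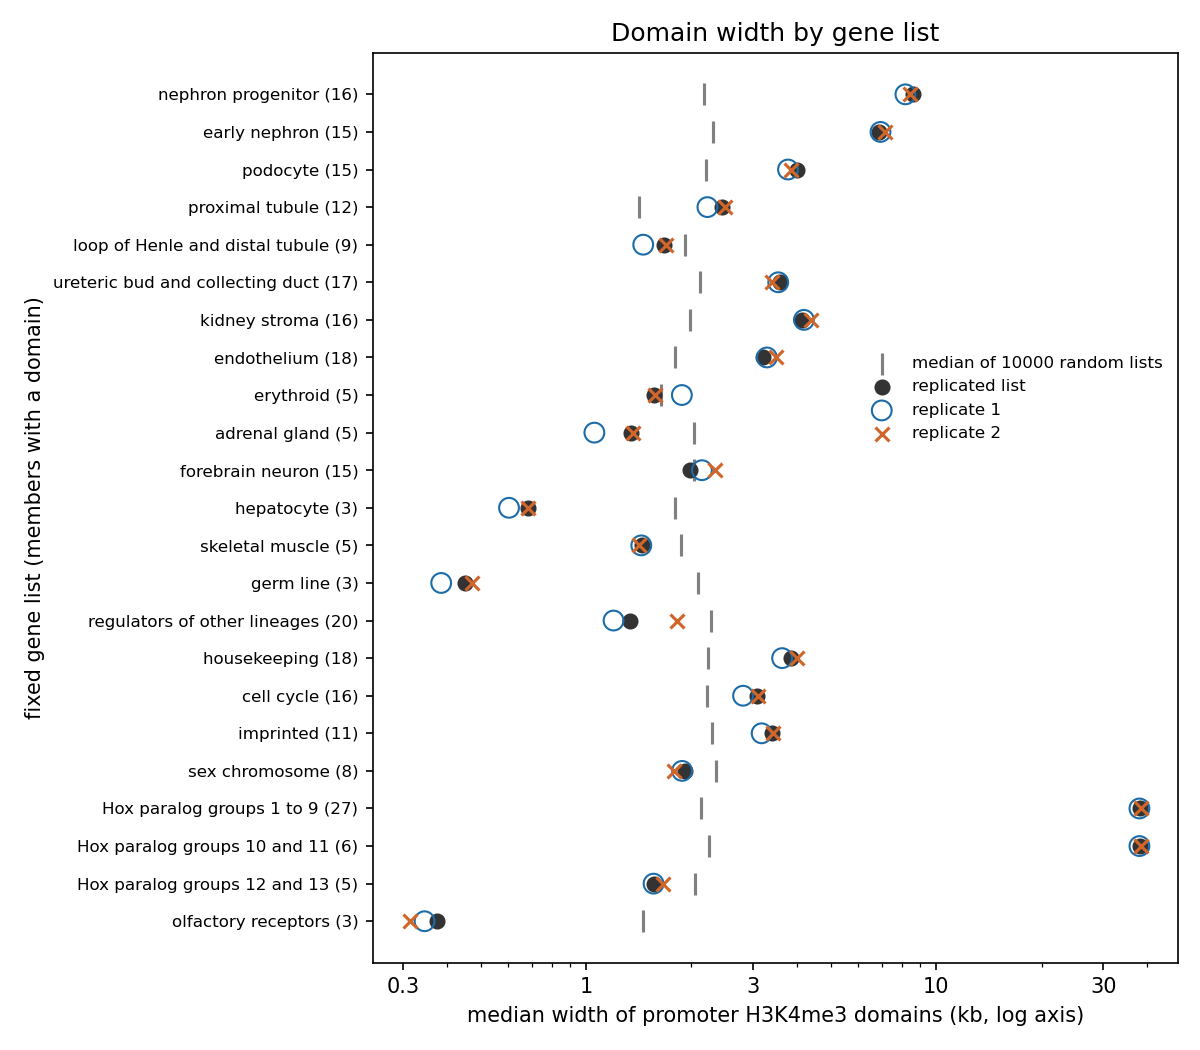
Median width of promoter H3K4me3 domains by gene list (x axis, kb, log scale; members with a domain in parentheses on the y axis) in the replicated list (filled circles), replicate 1 (open circles) and replicate 2 (crosses); grey bars are the median over 10000 random lists matched on CpG class. Nephron progenitor and early nephron medians lie at 8.61 and 6.87 kb in the replicated list, and the germ line median at 0.450 kb.

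All genes of the sex chromosome list were marked. Xist, the noncoding RNA of the inactive X chromosome, had a domain of 3.44 ± 0.612 kb (n = 2) with a fold of 25.7. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had folds of 19.7, 20.3, 18.4 and 17.7, and their X-linked homologs Ddx3x, Kdm6a, Kdm5c and Eif2s3x folds of 75.4, 61.2, 73.9 and 66.8. These folds divide by a control whose scaling is not given in the sources used here. These 4 Y-linked genes were the only ones on chromosome Y with a promoter peak in the replicated list, with the limit for near-identical copies given above.

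Of 22962 domains, 7331 (31.9%) lay more than 5 kb from any protein-coding TSS, with a median width of 0.627 kb against 2.08 kb for domains at a TSS. The widest of these lay at noncoding RNA genes: the lincRNA C230035I16Rik (chromosome 13: 23429376 to 23439184; 9.73 ± 0.0884 kb, n = 2; nearest coding gene Abt1 at 5.51 kb), Malat1 (chromosome 19: 5794869 to 5804293; 9.30 ± 0.235 kb; nearest Scyl1) and Neat1 (chromosome 19: 5841003 to 5850308; 9.03 ± 0.777 kb; nearest Frmd8), both of them abundant nuclear RNAs. A domain of 9.04 kb lay within 2010111I01Rik, at Gm47585 and Gm47602, transcripts of unsettled type in the annotation (chromosome 13: 63272030 to 63281067). The last, classed as intronic, overlapped Hoxc5 and Hoxc6, 5.01 kb from Hoxc8 (chromosome 15: 102995620 to 103003622). The annotated start of the Hoxc6 gene (102998257) lay inside this domain, but only starts of protein-coding transcripts counted as coding TSSs. Its width was 9.46 ± 2.66 kb in the replicates' own lists (11.3 and 7.58 kb). The order given here follows widths in the replicated list.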

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

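The peak lists also held signal outside the chromosomes that the comparisons used. In the replicated list 11 peaks lay on 6 unplaced or unlocalised contigs, with folds from 2.58 to 48.6. They are named because any peak there is signal that the comparisons left out; no control sample was analysed to set a higher limit. Genes on these contigs were not examined.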

How the results depend on the processing

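The matching on fold, the lists without Hox genes, the middle and low CpG classes and the runs without the germ line list were chosen after seeing the data. Of 92 recomputed values of the main comparisons, 85 stayed the same by rules set for each kind: direction and side of the threshold for tests, within 1.5 times the first value for counts, and within its confidence interval for the share of peaks kept. Counts called the same still changed: lists with more peaks fell from 10 to 7 with fold of at least 5, and lists with wider domains from 12 to 9 without replicate 2. Of the others 6 moved and 1 lost its call. Replicate overlap, promoter share and the CpG contrast kept theirs in all runs made of them. Replicate 1 sharing ran from 70.8% (reciprocal overlap) to 96.9% (fold of at least 5), and replicate 2 sharing from 75.5% to 91.3%. The promoter share ran from 49.5% (outermost TSS) to 69.0% (fold of at least 5), and random placement in place of shifts gave 4.33% by chance. With lncRNA genes added, 17767 of 35227 genes (50.4%) carried a peak. The kidney difference ran from 3.23 percentage points (high CpG promoters without the germ line list, exact p = 0.326, call lost) to 52.8 (low CpG promoters), and was 26.2 without the germ line list (exact p = 6.24e-05).

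The share of pooled peaks kept moved to 97.9% with −log10 q of at least 5 and to 100% with fold of at least 5; any overlap of 1 bp with both replicates would keep 82.4%. Within the high CpG class the lists with more peaks went from 10 to 0 and those with fewer from 7 to 1; most of the latter have few members in that class. There erythroid, adrenal gland, hepatocyte and skeletal muscle genes stood at 100% and regulators of other lineages at 94.7%, on the other side of the remaining genes, none past the threshold. Joining gaps of up to 3 kb turned the median of regulators of other lineages to 2.79 kb, above random lists (adjusted permutation p = 0.234); the cause was not tested. Matched on fold in place of CpG class, lists with narrower domains fell from 4 to 1. Regulators of other lineages (1.34 kb) were then no longer below random lists, and forebrain neuron genes (1.99 kb) lay above them (adjusted permutation p = 0.0449). Of 239 list occupancy values and 203 list widths, 22 and 12 lost a call and 2 and 2 gained 1, those named above as changing side included. The proximal tubule width call was lost with gaps of 0 bp or up to 3 kb, without CpG matching and without replicate 2 (adjusted permutation p = 0.0524, 0.143, 0.476 and 0.0506). Of 491 widths of named genes, 218 moved by more than the SD of the replicates. Depth is unknown, so a promoter without a peak was not detected here rather than shown to be unmarked.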

Other observations

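The explanations weighed in this part were chosen after the results they bear on were seen. Some runs they draw on had been set beforehand: matching on CpG class, gaps of up to 3 kb and the outermost TSS. Families defined by gene symbol after the data were seen showed further contrasts (18 families, with Benjamini-Hochberg adjusted p of Fisher's exact tests for peaks and of permutation tests for widths). The tests for peaks compared each family with all other coding genes. They were not matched on CpG class, so they do not separate a family from the CpG content of its promoters. All 19 Sox genes carried a promoter peak (adjusted exact p = 0.00149), with a median domain of 3.62 kb, and Irx genes (6 of 6) had a median of 5.88 kb against 2.36 kb in random lists (adjusted permutation p = 0.000680, the smallest possible), with Irx5 at 11.5 kb and Irx4 at 1.11 kb. Replication-dependent histone genes were marked in 59 of 67 cases (adjusted exact p = 0.000242) in domains with a median of 3.30 kb. Of 33 claudin genes 14 were marked (adjusted exact p = 0.00690), yet in wide domains (median 3.05 kb, adjusted permutation p = 0.00874), and the neighbours Cldn6 and Cldn9 shared 1 of 12.0 kb. Keratin genes carried a peak in 8 of 53 cases (adjusted exact p = 2.81e-14), among them the simple epithelial Krt7, Krt8, Krt18 and Krt19. Cytochrome P450 genes did in 27 of 100 (adjusted exact p = 2.1e-15), the widest being Cyp26b1, which degrades retinoic acid, at 6.98 kb, and vomeronasal receptor genes in 1 of 331. Clustered protocadherins, genes of neuronal identity, were marked in 29 of 57 cases in narrow domains (median 0.542 kb against 1.82 kb, adjusted permutation p = 0.000680).

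Regulators of other lineages carried peaks in 20 of 21 cases, in narrow domains. Their CpG classes alone would give 20.3, so CpG class is in line with the number of peaks. The narrow width was itself defined against random lists matched on CpG class. With gaps of up to 1000 bp joined the median lay at percentile 0 of them. That is the same test, so it gives no separate evidence on CpG class. With gaps of up to 3 kb the median was 2.79 kb and no longer below such lists, so the narrow width itself depends on the gap. Among lists joined at 1000 bp and matched on fold it lay at percentile 80.3. Those lists were matched on fold in place of CpG class. Low CpG promoters had both lower folds and narrower domains than high CpG promoters. A place within the fold-matched lists therefore does not single out weak signal as an account of the width. Neurons in the tissue cannot be told apart from CpG class as a source of the peaks. Of forebrain neuron genes outside the high CpG class, 6 of 7 carried peaks against 4.07 from their classes (exact p = 0.0616). These 7 genes are too few to decide. Beyond the presence of neurons, no biological explanation was tested, since the design has 1 group.

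Among the fixed lists, germ line genes were the only ones called lower within the high CpG class. Of 10 germ line genes in the high CpG class, 8 had no peak (Asz1, Ddx4, Hormad1, Mael, Slc25a31, Sycp1, Sycp3 and Taf7l), although 98.6% of the whole class had one (odds ratio 288, Fisher's exact p = 6.86e-14). Reads shared with copies elsewhere would leave little unique sequence, but a median of 100% of the 32-mers at these 8 promoters, and at least 96.5% at each, occurred once in the genome. At their outermost TSS 100% of the 8 were still in the high class. This argues against a secondary TSS with high CpG content only for genes with more than 1 TSS, such as Ddx4. For a gene with 1 TSS, such as Asz1, the class there was fixed. The lack of a peak there was fixed for all 8 by how they were chosen. How many of the 8 have 1 TSS was not counted. Of all 162 high CpG genes without a peak, 75 did have under 50% unique 32-mers, against 0 of 200 marked high CpG promoters, so for many of those shared reads may matter. The protocadherin genes Pcdha1 to Pcdha9, also among the 162, had 70.6% to 90.6%. The 63 with at least 90% included the 8 germ line genes above, Hormad2 and Sycp2, which share symbol stems with them, and Spo11 and Msh4. Others among the 63, such as Otp, Dbx1 and Nkx2-5, were not on the germ line list. The 63 were not sorted by kind or tested as a group. No biological explanation was tested.

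The promoters of Ddx3y, Uty, Kdm5d and Eif2s3y had lower folds than those of their X-linked homologs, with a median ratio of 0.263 (0.351 in replicate 1 and 0.209 in replicate 2). Reads lost between the copies are argued against, since a median of 100% of the 32-mers at the Y-linked promoters occurred once in the genome, the lowest being Kdm5d at 88.4%. Fewer copies of chromosome Y in embryos of both sexes pooled could lower the fold, but the fold also divides by a control whose scaling is not given, so this stays open. In the high CpG class, promoters on chromosome X also had a lower median fold than autosomal ones (36.9 against 55.2), but the difference was small in the middle class (28.0 against 29.9) and absent in the low class (10.5 against 10.3). In the low class X was higher in both replicates (9.19 against 7.89 and 9.99 against 8.64), and no cause was tested.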
